A study of Mus musculus with 18 samples.

How the data were processed

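Total RNA was sequenced from the gastrocnemius, a mainly fast-fibre muscle of the calf, and the soleus, a mixed muscle beside it that is richer in slow fibres. The mice were 12 weeks old, fed chow and fasted for 4 h before harvest. Control mice carried a floxed Site-1 Protease gene (Mbtps1). Knockout mice carried the same allele with a Cre recombinase driven by the human skeletal actin promoter, which is active in skeletal muscle fibres. Muscles were snap frozen, RNA was extracted with RNA STAT-60 and treated with DNase, and ribosomal RNA was removed with the KAPA RiboErase kit, per the labels' protocols. The titles place 5 control and 4 knockout libraries in each muscle, 18 in all, whereas the series text states 4 per group; the titles were followed. No label says explicitly that the libraries came from separate mice. If they did not, the p-values measure only the spread between these samples.

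For each library the authors deposited read counts per Ensembl gene, and per the submitters' processing notes the tools were bcl2fastq, STAR 2.5.1a, Subread and featureCounts 1.4.6-p5 on the build GRCm38. The annotation release, the strand setting and the treatment of multi-mapped reads are not given in the sources used here. The deposited CPM values equalled the deposited counts rescaled to each library's total, to within 4.9e-10, and the deposited RPKM values equalled those CPM per kilobase of the listed gene length to within 4.4e-10. Only the deposited counts were used, since the CPM and RPKM hold the same information without the counting error. All 41388 listed features were Ensembl genes and 0 lines named anything else; 40254 of them (97.3%) took a symbol from the GENCODE mouse release 21 annotation of GRCm38. Coordinates are those of the deposited files. Genes that share reads with close relatives, such as Actc1 with other actins, Amy1 with other amylases, the myosin heavy chains and Calm3 with its relatives, are uncertain to the extent that the counting split such reads. Of 100 genes whose fold changes the text gives, 13 were overlapped by another gene whose mean count reached at least 10% of their own. These were Tmem267, Cntnap2, Ctnna3, Amy1, Srebf1, Ciart, Timp1, Mhrt, Tecrl, Sv2b, Phkg1, Bex1 and Macrod2. The widest gap was that of Mhrt, with a mean of 171 counts against 287941 for the overlapping Myh7 on the other strand.

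Library totals ran from 39.0 to 78.2 M counts. A gene with a count of 0 over a group was set to a floor of 3 counts over that group for a fold change, and ratios of very low counts carry exact 95% intervals. These floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Pairs of libraries of one group differed by 19.59 to 140.26 chi-square units per gene, so that no pair was close to sampling noise and none was merged.

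Counts were fitted in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood fit and F-test, Benjamini-Hochberg adjustment, threshold 0.05). Each muscle's knockout comparison used its own 9 libraries. The comparison of the muscles (soleus minus gastrocnemius controls) and the difference of the knockout effects (soleus minus gastrocnemius) used all 18 libraries in 4 groups, with no other covariate. Levels are CPM on TMM-scaled library sizes, as mean ± SD. Fold changes are log2 values from the edgeR fits with their standard errors (SE). Every adjusted p of a gene is from the edgeR test unless another tool is named.

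The 32 gene lists were compared with all other tested genes by camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists), with camera at an estimated correlation and fry as alternatives. The lists were S1P substrates and partners, cholesterol synthesis (SREBP2 targets), fatty acid synthesis (SREBP1 targets), ER chaperones and folding (ATF6 targets), integrated stress response (ATF4 targets), Golgi and COPII transport, lysosomal genes, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, mitochondrial regulators, fatty acid oxidation, TCA cycle, glycolysis and glycogen, TGF-beta, activin and BMP signalling, slow-fibre genes, fast-fibre genes, atrophy and protein breakdown, denervation and regeneration, extracellular matrix, clock genes, immediate-early and dissection stress, sex-linked genes, and markers of fibroblasts, endothelium, macrophages, lymphocytes, adipocytes, satellite cells, Schwann cells, smooth muscle, tendon and red blood cells. Several genes stand in more than 1 list, and muscle fibres themselves express part of the marker lists. A list score per library is the mean over members of the log2 CPM (plus 0.5 CPM) minus the gene's mean in that muscle. Exact two-sided permutation tests over 126 splits compared the matrix, macrophage, denervation, Schwann cell, clock and slow-fibre scores. Camera called each of these lists in a knockout comparison of the same data, and the permutation p-values are not adjusted over lists. Calls shared by the muscles were tested with Fisher's exact test per direction.

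Genes were named by a rule: Mbtps1 in each comparison; in each knockout comparison the 10 highest and 10 lowest changes past the threshold with mean log2 CPM of at least 1, all knockout libraries on one side of all controls and a symbol that is not a placeholder; up to 4 members of each list by smallest adjusted p; Mss51, Mstn, Gnptab, Srebf1, Srebf2 and Atf6 whatever their p; the 6 highest and 6 lowest between the muscles; and the 10 smallest adjusted p for the difference of knockout effects. This rule, the lists, the tests of genes, lists and shared calls, and the first set of alternatives were fixed before the data were examined. The tests of list scores and the list tests for the difference of knockout effects were not. Some tests of possible explanations were also chosen later, as stated where they are given. Genes outside the rule are said to have been chosen after their values were seen. The values of some genes that were called are not reported here, so counts of calls can exceed the genes named.

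That first set of alternatives comprised DESeq2 1.42.0, median-of-ratios (RLE) scaling, scaling without mitochondrial and non-coding structural RNA genes, no low-count filter, limma voom with quality weights, a log2 fold change of at least 1, 1 surrogate variable (sva 3.50.0), other sets of libraries in the fit, a block on the title number for comparisons across muscles, and leaving out each library. The share of counts from Ttn as a covariate and the omission of soleus knockout libraries 40 and 42 were added after the data were seen. RLE in place of TMM moved the median log2 fold change of all genes by at most 0.041 in size in any comparison (-0.009 in gastrocnemius, 0 in soleus, -0.041 between muscles, 0.034 for the difference).

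The tests were checked on simulated counts with 200 changed genes and the matrix list raised 1.5-fold. At 1.5-fold, 2-fold and 4-fold, edgeR recovered 34.3%, 70.1% and 87.9% for gastrocnemius (16393 genes), 38.8%, 68.7% and 90.9% for soleus (18087 genes), 40.3%, 62.7% and 86.4% between muscles and 19.4%, 52.2% and 74.2% for the difference of knockout effects (18494 genes each). It gave 0 calls of the wrong sign and 0 calls in simulations with no change. Each setting was simulated once from the fitted dispersions, with independent genes, no odd library and no other difference between the muscles. The real data hold correlated genes and libraries that stand apart, so these rates may flatter the tests. Among unchanged genes of the simulations with changed ones it made 8, 5, 2 and 2 false calls in these comparisons, and DESeq2 made 38, 23, 19 and 19. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.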

Results

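RNA-seq libraries of total, rRNA-depleted RNA were compared between mice described as lacking Site-1 Protease (S1P, gene Mbtps1) in skeletal muscle and floxed controls, in the gastrocnemius and the soleus. S1P is a Golgi protease that cleaves membrane-bound transcription factors such as the SREBPs and ATF6. The design asks what loss of S1P changes in each muscle. No control carrying Cre alone stands among the libraries, so no knockout comparison can tell loss of S1P from an effect of the Cre allele. In the gastrocnemius, the 5 control libraries held 51.2 (replicate 1), 40.7 (3), 39.0 (4), 42.2 (5) and 50.8 (8) M counts. The 4 libraries labelled knockout held 46.7 (2), 46.7 (6), 41.9 (7) and 55.8 (9). In the soleus, the 5 control libraries held 58.6 (34), 64.7 (36), 78.2 (37), 46.5 (38) and 53.0 (41) M counts. The 4 labelled knockout there held 46.2 (35), 68.3 (39), 47.0 (40) and 53.6 (42). Mitochondrially encoded genes took 7.4% to 8.87% of counts in gastrocnemius libraries and 9.43% to 12.66% in soleus libraries.

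Mbtps1 itself (ENSMUSG00000031835, GRCm38 chromosome 8, 119508156 to 119558761) was not lower in the libraries labelled knockout. In gastrocnemius controls its level was 33.1, 34.8, 29.4, 30.1 and 29.5 CPM (replicates 1, 3, 4, 5 and 8), and in the libraries labelled knockout 35.6, 34.5, 42.6 and 37 CPM (replicates 2, 6, 7 and 9). The group means were 31.4 ± 2.42 (SD, n = 5) and 37.4 ± 3.59 CPM (SD, n = 4), a log2 fold change of 0.26 (SE 0.08, adjusted p = 0.0945). Soleus controls held 31.9, 33.6, 30.9, 31.6 and 34.4 CPM (replicates 34, 36, 37, 38 and 41; mean 32.5 ± 1.47, SD, n = 5). The soleus libraries labelled knockout held 35.9, 31.3, 36.4 and 34.9 CPM (replicates 35, 39, 40 and 42; 34.6 ± 2.32, SD, n = 4), a log2 fold change of 0.10 (SE 0.07, adjusted p = 0.754). The deleted exon is not given in the sources used here, and counts over a whole gene cannot resolve the loss of an exon. The level of Mbtps1 therefore neither bears out nor contradicts the labels. All directions rest on the labels, as the library titles give them.

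In the gastrocnemius, the libraries labelled knockout carried Sox14, a transcription factor gene of neural development that had 0 counts in all 5 controls. It reached 233 to 328 counts in each of the 4 libraries labelled knockout (6.4 ± 0.975 CPM, SD, n = 4), at least 448-fold higher against a floor of 3 counts over the control group (adjusted p = 7.72e-07). Sarcolipin (Sln), an inhibitor of the sarcoplasmic reticulum calcium pump, rose from 0.511 ± 0.14 to 10.8 ± 9.12 CPM (log2 fold change 4.40, SE 0.58, adjusted p = 0.00852). The cardiac actin gene Actc1, an embryonic isoform in skeletal muscle, rose from 149 ± 82.9 to 863 ± 211 CPM (2.53, SE 0.40, adjusted p = 0.0218). The muscle-secreted peptide gene Ostn (musclin) fell from 13.1 ± 3.67 to 2.7 ± 0.711 CPM (log2 fold change -2.27, SE 0.24, adjusted p = 0.00136). Myostatin (Mstn), a secreted inhibitor of muscle growth, fell from 85.7 ± 13.1 to 41.3 ± 9.46 CPM (log2 fold change -1.05, SE 0.17, adjusted p = 0.0115).

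**Figure D1:**
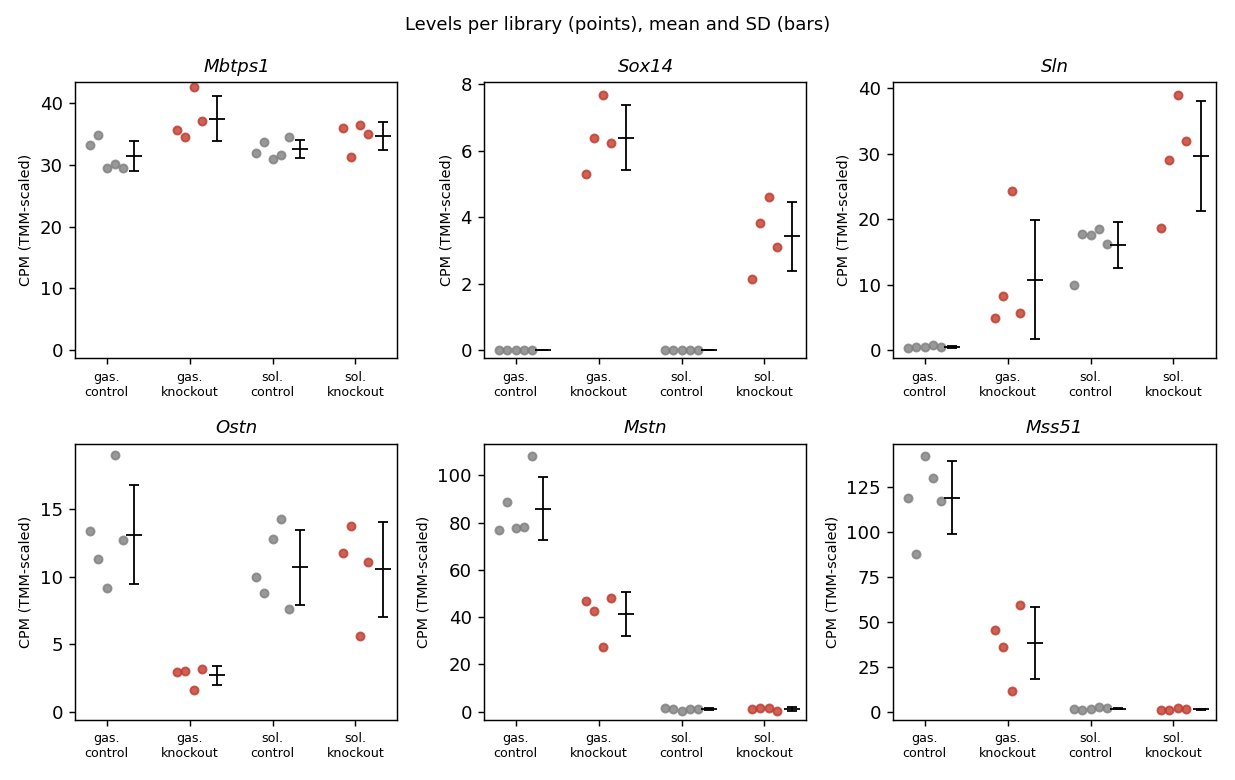
TMM-scaled CPM of 6 genes (y axis) in each library (points) of the 4 groups, with the mean and SD beside them (bars). Mbtps1 was not lower in the libraries labelled knockout, Sox14 was at 0 in gastrocnemius controls and at 6.4 ± 0.975 CPM in the libraries labelled knockout, and in soleus controls Mstn was at 1.04 ± 0.421 and Mss51 at 1.75 ± 0.495 CPM.

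Among called genes with mean log2 CPM of at least 1 and no overlap between the groups, the others with the highest changes were Shisal1 (log2 fold change 3.14), Ppfia4 (1.62), the G protein regulator Rgs2 (1.57), Cgref1 (1.57), the cell cycle factor E2f2 (1.57), the metallothionein Mt3 (1.53) and the protease inhibitor Serpinb1a (1.47). Within the same limits, those with the lowest were the T cell co-stimulatory receptor Cd28 (-2.47), Snph (-1.78), Tmem267 (-1.40), the potassium channel subunit Kcnf1 (-1.34), Cntnap2 (-1.22), the cell adhesion gene Ctnna3 (-1.18), the amylase Amy1 (-1.11), the zinc transporter Slc30a2 (-1.10) and Ankrd6 (-1.07). Their adjusted p ran from 3.12e-05 for Cd28 to 0.0438 for Tmem267. Among 16393 genes tested, 619 changed (290 higher, 329 lower), 132 of them by at least 2-fold, and 3057 had an unadjusted p under 0.05. The count was 1235 with DESeq2, 1028 with limma voom and 1163 with 1 surrogate variable. It fell to 261, 278, 206 and 354 without controls 1, 4, 5 and 8 and to 211, 287 and 394 without knockout libraries 6, 7 and 9, and was 1080 without knockout library 2. Single calls were also lost without 1 library: Actc1 without control 1 or 5 or knockout 6 or 7 (adjusted p = 0.0516 to 0.065). So were Ctnna3 without control 1 or 5 or knockout 7 (0.0596 to 0.0655) and Cntnap2 without control 5 or knockout 6 (0.0575 and 0.0775). The same held for Tmem267 without control 1, 3, 4, 5 or 8 or knockout 9 (0.0679 to 0.111) and for Slc30a2 without any 1 control or knockout 6 (0.0608 to 0.12). Without a low-count filter Tmem267 (0.0728), Slc30a2 (0.0797), Cntnap2 (0.0548) and Ctnna3 (0.0528) lost their calls, and Mstn did in a fit of all 18 libraries (0.0937).

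Genes of the denervation and regeneration list, which immature, regenerating or denervated fibres express, were higher as a group in the gastrocnemius libraries labelled knockout. Of 23 measured, 8 rose and 3 fell (11 and 4 adjusted over the list alone), with a median log2 fold change of 0.64. Besides Sln, the fetal acetylcholine receptor subunit Chrng rose 4.03-fold (0.359 ± 0.0864 to 1.45 ± 0.646 CPM, adjusted p = 0.00601) and the subunit Chrna1 rose 2.5-fold (adjusted p = 0.00861). Chosen after their values were seen, the transcription factors Runx1 (log2 fold change 1.15) and Myod1 (0.64) and the stress gene Gadd45a (0.91) rose as well. The members that fell were Musk, the receptor kinase of the neuromuscular junction (83.7 ± 11.4 to 45.6 ± 7.47 CPM, log2 fold change -0.87, SE 0.13, adjusted p = 0.00429), and, chosen after their values were seen, the adult muscle sodium channel Scn4a (-0.29, adjusted p = 0.0418) and the cadherin Cdh15 (-0.32, adjusted p = 0.0446). The list differed from other genes by camera (adjusted p = 6.68e-06), though not with an estimated correlation (adjusted p = 0.293 with an estimated correlation). Its score was higher in the libraries labelled knockout by an exact permutation test (p = 0.00794, the smallest that 126 splits can give, not adjusted over lists). Runx1 lost its call without control 5 or knockout 7 (adjusted p = 0.0534 and 0.0545) and in the fit of all 18 libraries (0.0866), as did Gadd45a (0.0636) and Myod1 (0.354) there. Scn4a lost it without control 1, 4, 5 or 8 or knockout 6, 7 or 9 (0.0788 to 0.107), and Cdh15 without any 1 library (0.0528 to 0.128).

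Extracellular matrix genes were positive in 26 of 26 members in the gastrocnemius, with a median log2 fold change of 0.38, but 0 of them passed the threshold over all genes, against 15 adjusted over the list alone. The tissue inhibitor of metalloproteinases Timp1 had the smallest p (log2 fold change 1.46, SE 0.41, adjusted p = 0.0642; 6 of 17 alternatives put it past the threshold). The matrix list passed camera (adjusted p = 1.65e-08; adjusted p = 0.631 with an estimated correlation), and its score gave p = 0.0397 in an exact permutation test. Macrophage markers were positive in 11 of 12 members (median 0.64, camera adjusted p = 0.000277; adjusted p = 0.631 with an estimated correlation; exact permutation p = 0.0238 for the score). None passed over all genes by edgeR and 2 did adjusted over the list alone, and the smallest p was that of the mannose receptor Mrc1 (log2 fold change 0.41, SE 0.13, adjusted p = 0.0933). Of 4 measured lymphocyte markers 1 rose, the pan-leukocyte phosphatase Ptprc (3.82 ± 0.74 to 7.59 ± 0.953 CPM, adjusted p = 0.00329; list adjusted p = 0.00893; adjusted p = 0.293 with an estimated correlation). Of 10 satellite cell markers 1 rose, the muscle stem cell factor Pax7 (log2 fold change 0.85, SE 0.18, adjusted p = 0.0219; list adjusted p = 0.022; adjusted p = 0.293 with an estimated correlation), with 2 adjusted over the list alone. Pax7 lost its call without control 1, 4 or 5 or knockout 6, 7 or 9 (adjusted p = 0.0512 to 0.0775) and in the fit of all 18 libraries (0.137). Knockout library 7 stood apart in the matrix, macrophage and denervation lists, and without it the median of the matrix list was 0.25, that of macrophage markers 0.29 and that of the denervation list 0.36, with 24 of 26, 11 of 12 and 16 of 23 members positive.

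**Figure D2:**
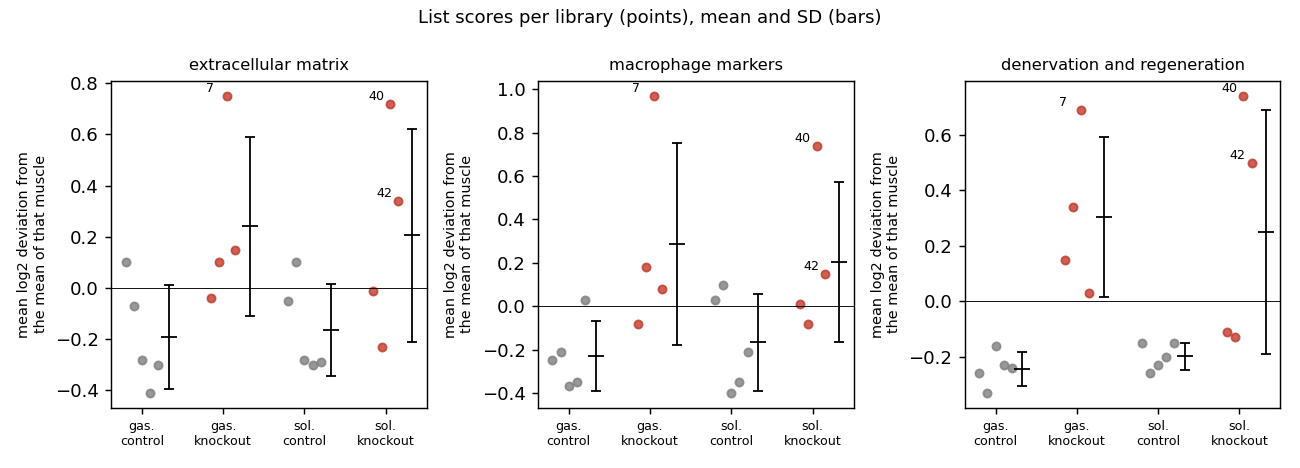
Mean log2 deviation of each library (points) from the mean of its muscle (y axis) for the matrix, macrophage and denervation lists in the 4 groups, with mean and SD (bars); libraries 7, 40 and 42 are numbered. In gastrocnemius the matrix score was -0.19 ± 0.2 in controls and 0.24 ± 0.35 in the libraries labelled knockout, and in soleus -0.16 ± 0.18 and 0.21 ± 0.42.

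Lists of oxidative phosphorylation, mitochondrial regulators, fatty acid oxidation and Golgi transport had slightly negative medians in the gastrocnemius libraries labelled knockout. Nuclear-encoded oxidative phosphorylation genes had a median log2 fold change of -0.09 with 12 of 78 positive (camera adjusted p = 0.000489; adjusted p = 0.8 with an estimated correlation). In their scores knockout libraries 2 and 6 were low (-0.14 and -0.21), while 7 and 9 (0.11 and 0.04) lay inside the range of controls (-0.16 to 0.17). The 3 lowest scores, those of knockout libraries 2 and 6 and control 3 (-0.16), came with the highest shares of counts from Ttn (12.56%, 11.27% and 12.08%), whereas the most counted gene took 7.3% to 9.19% in the other gastrocnemius libraries. Mitochondrial regulators had a median of -0.10 with 6 of 24 positive (camera adjusted p = 0.0188; adjusted p = 0.375 with an estimated correlation). Fatty acid oxidation genes had a median of -0.06 with 6 of 26 positive (camera adjusted p = 0.0442; adjusted p = 0.8 with an estimated correlation), and their scores in all 4 libraries labelled knockout (-0.06 to -0.01) lay inside the range of controls (-0.06 to 0.15). No member of these 3 lists passed by edgeR over all genes or adjusted over the list alone. Mss51, a muscle gene that restrains mitochondrial respiration, lay at 119 ± 20.2 CPM in controls and 38.1 ± 20 in the libraries labelled knockout (log2 fold change -1.64, SE 0.43). It missed the threshold (adjusted p = 0.0892) although the groups did not overlap. It passed with DESeq2 (0.00311), limma voom (0.0349), the fit of all 18 libraries (0.0158) and without knockout library 7 (0.0179). Golgi and COPII transport genes had a median of -0.13, with 2 of 24 lower (4 adjusted over the list alone), the coat protein gene Sec13 (log2 fold change -0.34, adjusted p = 0.0219) and the SNARE gene Gosr2 (-0.29, adjusted p = 0.0409). That list passed camera (adjusted p = 0.000277; adjusted p = 0.306 with an estimated correlation). Sec13 lost its call without control 4, 5 or 8 or knockout 6 or 7 (adjusted p = 0.0518 to 0.0775), and Gosr2 without control 1, 4, 5 or 8 or knockout 2, 6 or 7 (0.0623 to 0.135).

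Of 16 slow-fibre genes 1 fell over all genes, the slow myosin light chain Myl2 (88.8 ± 16.6 to 45.9 ± 8.17 CPM, log2 fold change -0.95, SE 0.16, adjusted p = 0.0113; 0.0588 without knockout library 7), against 1 higher and 3 lower adjusted over the list alone. The slow-fibre median was -0.29 (camera adjusted p = 0.0074; adjusted p = 0.631 with an estimated correlation). Knockout library 9 stood apart in its score (-0.62, other libraries labelled knockout -0.16 to 0.05, controls -0.09 to 0.3), and an exact permutation test of the scores gave p = 0.0635. Fast-fibre genes had a median of -0.12 with 0 called over all genes and 1 lower adjusted over the list alone (0.0261; adjusted p = 0.8 with an estimated correlation). Clock genes, which drive daily rhythms, had a median of -0.16, and 3 of 16 fell on either adjustment, over all genes and adjusted over the list alone, among them the repressor Ciart (11.2 ± 0.941 to 6.14 ± 1.66 CPM, adjusted p = 0.011) and Hlf (log2 fold change -0.52, adjusted p = 0.0219). Camera gave adjusted p = 0.000858 for the clock list and adjusted p = 0.293 with an estimated correlation. Directional fry gave adjusted p = 0.0478, and an exact permutation test of the scores gave p = 0.0238, not adjusted over lists. Hlf lost its call without control 4 or 5 or knockout 6 (adjusted p = 0.0534 to 0.0796) and in the fit of all 18 libraries (0.0707). The time of harvest is not given in the sources used here.

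In the gastrocnemius, 5 lists of S1P substrates and the pathways below them did not move to one side against other genes by camera. Golgi transport, given above, was lower by camera at the preset correlation. These are mRNA levels, which do not measure cleavage by S1P. S1P substrates and partners had 1 of 18 lower (1 adjusted over the list alone), the sterol and lipid regulator Srebf1 (48.3 ± 6.8 to 32 ± 4.91 CPM, log2 fold change -0.59, SE 0.12, adjusted p = 0.0182). Srebf1 lost its call without control 5 or knockout 6 or 7 (adjusted p = 0.0518 to 0.0636). Log2 fold changes of Srebf2 (0.11, adjusted p = 0.469), Atf6 (0.06, adjusted p = 0.688) and Gnptab, a lysosomal targeting enzyme cut by S1P (-0.04, adjusted p = 0.853), missed the threshold. Cholesterol synthesis genes had 1 of 25 lower (1 adjusted over the list alone), Hsd17b7 (log2 fold change -0.60, adjusted p = 0.0297; 0.0522 to 0.0934 without control 3, 5 or 8 or knockout 6, and 0.113 in the fit of all 18 libraries). Fatty acid synthesis genes had 2 of 20 lower (2 adjusted over the list alone), Srebf1 and the malic enzyme Me1 (163 ± 13.6 to 117 ± 10.4 CPM, adjusted p = 0.00598). ER chaperones, with 0 of 22 called by edgeR, and integrated stress response genes, with 0 of 23, had medians of -0.01 and 0.00 and 0 calls adjusted over the list alone. Camera adjusted p for these 5 lists were 0.671, 0.33, 0.185, 0.807 and 0.874. The mixed test of fry, which is blind to the sign of a change and makes no comparison with other genes, gave adjusted p = 0.00104, 0.000126, 0.00171, 0.419 and 0.233, and passed for 14 of the 32 lists. The test pointed down for S1P substrates against a median of 0.03 and a mean of 0.04. It pointed down for cholesterol synthesis (median 0.01, mean -0.04) and for ER chaperones (median -0.01, mean 0.02), and up for the integrated stress response (median 0.00, mean 0.03).

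Among the remaining lists in the gastrocnemius, 2 of 13 adipocyte markers rose (2 adjusted over the list alone), the muscle-expressed carbonic anhydrase Car3 (1240 ± 118 to 1930 ± 281 CPM, adjusted p = 0.00364) and the thermogenic uncoupler Ucp1 (0.142 ± 0.119 to 1.11 ± 0.155 CPM, adjusted p = 0.00732). Their list had a median of -0.07 and a mean of 0.13 with camera pointing up (adjusted p = 0.361). TGF-beta, activin and BMP signalling had 1 of 34 higher, Tgfb1 (log2 fold change 0.55, adjusted p = 0.015; 0.0563 without knockout library 6), and 1 lower, Mstn (1 and 3 adjusted over the list alone; list adjusted p = 0.335). Of 36 lysosomal genes 1 fell, the acid glucosidase Gaa (361 ± 19.4 to 298 ± 14.2 CPM, adjusted p = 0.03; list adjusted p = 0.33), which lost its call without control 1, 4, 5 or 8 or knockout 6 or 9 (0.0512 to 0.11). Of 20 TCA cycle genes pyruvate carboxylase (Pcx) fell (99.6 ± 5.54 to 70.1 ± 9.54 CPM, adjusted p = 0.00811; list adjusted p = 0.29). Of 27 glycolysis and glycogen genes the lactate exporter Slc16a3 fell (406 ± 23.3 to 300 ± 38 CPM, adjusted p = 0.0117; 0.0531 without knockout library 6 and 0.399 in the fit of all 18 libraries), in a list with median -0.03 and mean 0.01 whose test pointed down (adjusted p = 0.562). Each of these 3 lists had 1 lower call adjusted over the list alone. Camera adjusted p was 0.113 for mitochondrially encoded mRNAs, 0.213 for atrophy genes, 0.113 for fibroblast, 0.275 for endothelial, 0.176 for Schwann cell and 0.33 for smooth muscle genes. It was 0.874 for tendon and 0.645 for red blood cell genes, 0.75 for immediate-early genes and 0.524 for sex-linked genes. None of these 10 lists held a member past the edgeR threshold over all genes, and adjusted over the list alone only smooth muscle did, with 1 lower.

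**Figure D3:**
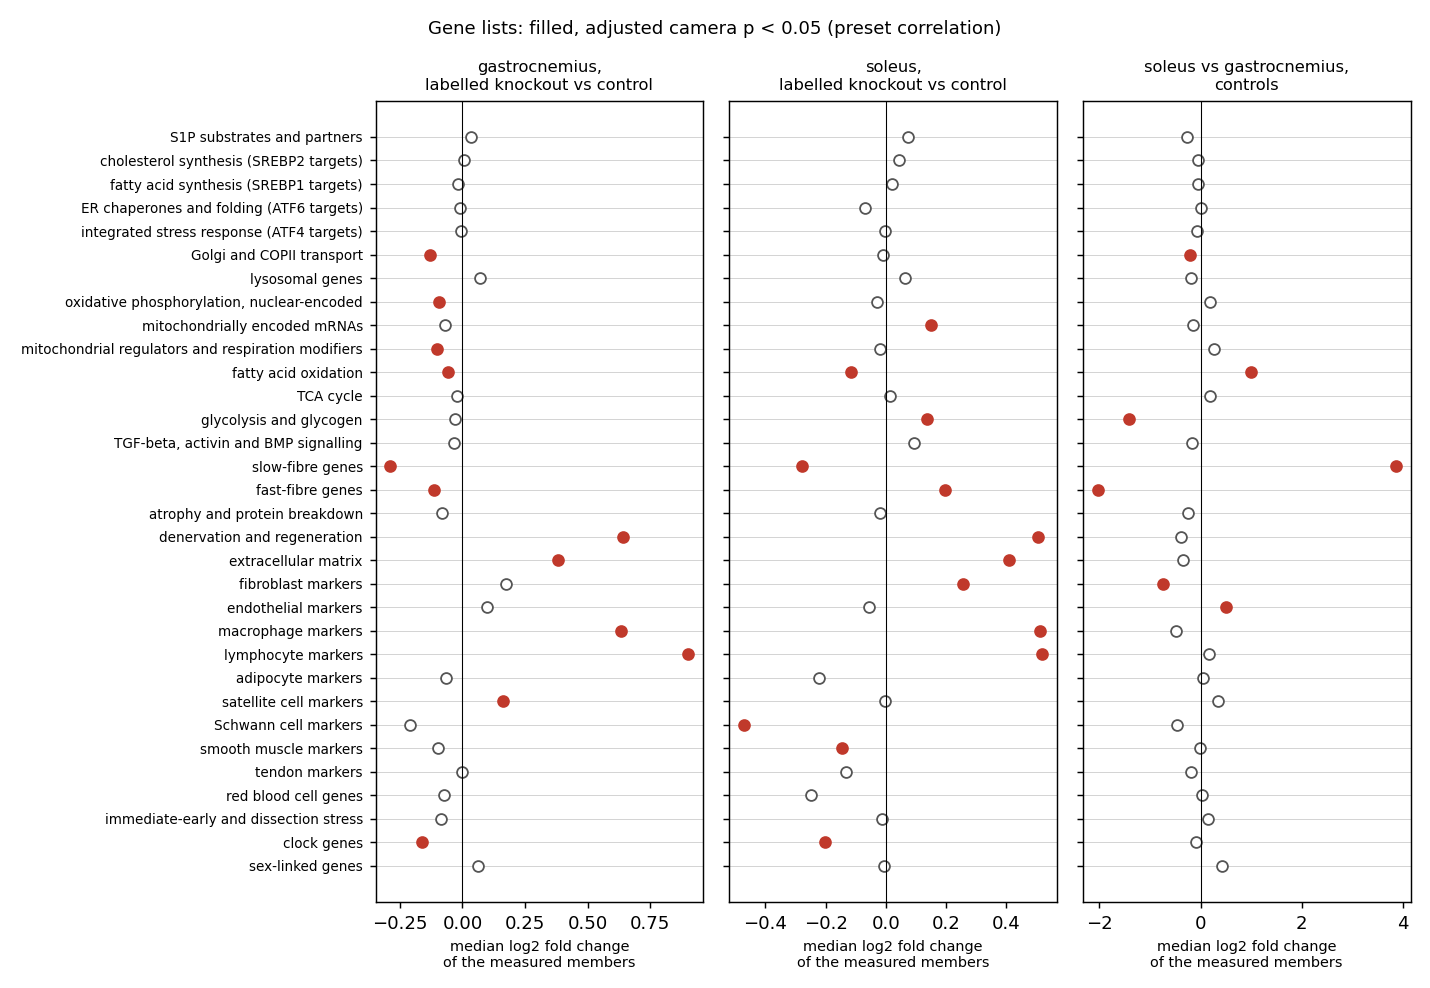
Median log2 fold change of the measured members of each of the 32 lists (x axis) in the 3 comparisons, filled where the adjusted camera p at the preset correlation passed 0.05. The matrix and denervation lists lie at 0.38 and 0.64 in gastrocnemius and at 0.41 and 0.50 in soleus, and slow-fibre genes at 3.86 between the muscles.

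In the soleus, 10 genes changed in the libraries labelled knockout, 7 higher and 3 lower. Of these, Mfhas1, a leucine-rich repeat gene, rose from 10.7 ± 0.486 to 18.8 ± 1.74 CPM (log2 fold change 0.83, SE 0.08, adjusted p = 0.000852). Ankyrin 2 (Ank2), a membrane adaptor, rose from 121 ± 8.7 to 173 ± 13.3 CPM (0.53, SE 0.07, adjusted p = 0.0181). The Wnt pathway ligand Rspo3 fell from 10.3 ± 1.04 to 4.54 ± 1.18 CPM (log2 fold change -1.17, SE 0.16, adjusted p = 0.0168). Ctnna3 (-0.89, SE 0.13, adjusted p = 0.0297) and dystrophin, Dmd (407 ± 10.8 to 273 ± 32.2 CPM, log2 fold change -0.56, SE 0.08, adjusted p = 0.0221), fell as well. Others, chosen after their values were seen, lay at low levels. Sox14 had 1 count over the 5 controls and 816 over the 4 libraries labelled knockout, a ratio of 1140 (95% counting interval 204 to 45200, adjusted p = 4.99e-07). Maats1 had a ratio of 13.9 (8.67 to 23.6), Fam71e2 of 23.8 (9.8 to 75.1) and the sperm channel gene Catsperg1 of 3.28 (2.77 to 3.91), with adjusted p of 0.0297, 0.0135 and 0.0226.

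These 10 came from 18087 genes tested, of which 1481 had an unadjusted p under 0.05. DESeq2 called 166 genes, the test without a low-count filter 48, the fit of all 18 libraries 28, 1 surrogate variable 4 and a log2 fold change of at least 1 kept 6. The count was 66 without knockout library 35, 4 without control 34 and 3 without control 37. Sox14 and Mfhas1 passed in the 18 alternatives that set no limit on the fold change, and at a log2 fold change of at least 1 Mfhas1 was not kept. Without control 34 the calls of Ank2 (adjusted p = 0.0753), Rspo3 (0.0753), Ctnna3 (0.104), Dmd (0.0843), Maats1 (0.104) and Catsperg1 (0.0753) were lost, and without control 37 those of the same 6 and Fam71e2 (0.0592 to 0.0969). Calls were also lost without control 36 (Catsperg1, Ctnna3 and Dmd, 0.0548 to 0.0725), control 38 (Ank2, Ctnna3, Dmd and Maats1, 0.0578 to 0.105) or control 41 (Maats1, Catsperg1 and Dmd, 0.066 to 0.0939). The same held without knockout library 39 (Maats1 and Catsperg1, 0.0837 and 0.0626), 40 (Maats1, Catsperg1 and Ctnna3, 0.0656 to 0.118) or 42 (Catsperg1, 0.0631). With 1 surrogate variable the calls of Rspo3 (0.0842), Ctnna3 (0.0746), Dmd (0.0842), Maats1 (0.0842), Fam71e2 (0.0682) and Catsperg1 (0.111) were lost, and in the fit of all 18 libraries those of Ctnna3 (0.0781), Dmd (0.0581) and Catsperg1 (0.165). With the share of counts from Ttn as a covariate, added after seeing the data, Ank2 (0.0836), Fam71e2 (0.359), Maats1 (0.467), Rspo3, Dmd and Catsperg1 (0.724 each) and Ctnna3 (1) lost theirs. Without both knockout libraries 40 and 42, added likewise, Dmd (0.0579), Maats1 (0.164), Ctnna3 (0.181), Fam71e2 and Catsperg1 (0.266 each) did.

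Soleus gene groups moved in both directions while 0 of their members passed the edgeR threshold over all genes. The matrix list was positive in 25 of 26 members (median 0.41, camera adjusted p = 2.69e-11; adjusted p = 0.502 with an estimated correlation). Denervation and regeneration genes were positive in 18 of 23 (0.50, 2.42e-07; adjusted p = 0.458 with an estimated correlation) and macrophage markers in 11 of 12 (0.51, 4.15e-06; adjusted p = 0.502 with an estimated correlation). Chrng, at 0.363 ± 0.106 and 1.51 ± 0.84 CPM, had the smallest p of the denervation list (adjusted p = 0.083), which had 6 higher adjusted over the list alone. Lyz2, the macrophage lysozyme, had that of its list (log2 fold change 0.79, adjusted p = 0.476). Knockout libraries 40 and 42 stood apart in these lists. Without them, an alternative added after seeing the data, the medians were 0.04 for the matrix (adjusted p = 0.268), 0.07 for denervation (0.15) and 0.12 for macrophages (0.052). Exact permutation tests of the scores gave p = 0.127 for the matrix, 0.0873 for macrophages and 0.00794 for denervation. Lymphocyte markers (median 0.52, adjusted p = 0.0138; adjusted p = 0.458 with an estimated correlation) and fibroblast markers (0.26, 0.0207; adjusted p = 0.609 with an estimated correlation) were higher too. So were the mitochondrially encoded mRNAs, positive in 13 of 13 (0.15, adjusted p = 0.00111; adjusted p = 0.609 with an estimated correlation), in libraries whose mitochondrial share was 11.2% ± 1.25 (SD, n = 4) against 9.83% ± 0.432 in controls (SD, n = 5). Knockout library 39 stood apart in these mRNAs (score 0.35, other libraries labelled knockout -0.09 to 0.06, controls -0.16 to 0.02), as library 40 did in fibroblast markers (0.46, others -0.17 to 0.09, controls -0.25 to 0.21). Lymphocyte scores were above controls (-0.2 to 0.05) in libraries 40 and 42 (0.25 and 0.26) and within them in 35 and 39 (-0.09 and 0.04).

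By list medians, slow-fibre genes were lower in the soleus libraries labelled knockout and fast-fibre and glycolytic genes higher, though not in every library. The slow-fibre list was positive in 2 of 16 members, with 1 higher and 9 lower adjusted over the list alone (median -0.28, camera adjusted p = 2.51e-08; adjusted p = 0.458 with an estimated correlation), and Myl2 lay at 1320 ± 143 and 796 ± 151 CPM (log2 fold change -0.72, SE 0.13, adjusted p = 0.0851). Fast-fibre genes had a median of 0.20 (0.00811; adjusted p = 0.609 with an estimated correlation) and glycolysis and glycogen genes of 0.14 (0.00259; adjusted p = 0.609 with an estimated correlation), each with 1 higher adjusted over the list alone. Knockout library 42 stood apart the other way, with a fast-fibre score of -0.67 (controls -0.46 to 0.16) and a glycolysis score of -0.2 (controls -0.14 to 0.07), both under every control, and a slow-fibre score of 0.07 within theirs (-0.01 to 0.19). Library 40 had the lowest slow-fibre score (-0.39, against -0.12 and -0.07 in 35 and 39), and an exact permutation test of these scores gave p = 0.0397. Lower medians were also found for fatty acid oxidation (-0.12, adjusted p = 9.88e-05; adjusted p = 0.609 with an estimated correlation) and for clock genes (-0.20, 0.001; adjusted p = 0.458 with an estimated correlation; exact permutation p = 0.0635 for the score) with 1 lower adjusted over the list alone. Knockout libraries 40 and 42 had fatty acid oxidation scores under all controls (-0.12 and -0.25) and 35 and 39 did not (-0.05 and 0.13, controls -0.06 to 0.15), and the clock score of library 35 (0.09) lay within controls (-0.05 to 0.18). Medians were lower as well for Schwann cell markers (-0.47, camera adjusted p = 0.00202; adjusted p = 0.609 with an estimated correlation; exact permutation p = 0.294 for the score, with every library labelled knockout inside the range of controls) and smooth muscle markers (-0.15, camera adjusted p = 0.00751; adjusted p = 0.502 with an estimated correlation). Ciart lay at 11.5 ± 1.23 and 7.33 ± 2.13 CPM (adjusted p = 0.293).

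In the soleus lists that missed the camera threshold, adjusted p was 0.0585 for S1P substrates, 0.892 for cholesterol synthesis, 0.927 for fatty acid synthesis, 0.157 for ER chaperones and 0.892 for the integrated stress response. It was 0.448 for Golgi transport, 0.107 for lysosomal genes, 0.151 for oxidative phosphorylation, 0.165 for mitochondrial regulators and 0.892 for the TCA cycle. For TGF-beta signalling it was 0.165, with 0.892 for atrophy genes, 0.341 for endothelial, 0.153 for adipocyte, 0.794 for satellite cell, 0.202 for tendon and 0.0542 for red blood cell genes, 0.448 for immediate-early genes and 0.871 for sex-linked genes. Median and test differed in sign for cholesterol synthesis (median 0.04, mean 0.01, down), the TCA cycle (0.01, mean -0.01, down), atrophy genes (-0.02, mean 0.08, up), satellite cell markers (0.00, mean 0.10, up) and immediate-early genes (-0.01, mean 0.01, up). The atrophy list had 2 higher adjusted over the list alone, and its smallest p was that of the receptor Eda2r (log2 fold change 0.88, SE 0.16, adjusted p = 0.0918). Log2 fold changes of Srebf1 (0.12, adjusted p = 0.775), Srebf2 (0.09, 0.882), Atf6 (0.00, 0.999), Gnptab (0.17, 0.648), Mss51 (-0.34, 0.767) and Mstn (0.15, 0.966) missed the threshold, and Mstn lay at 1.04 ± 0.421 and 1.13 ± 0.661 CPM.

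The calls of the 2 muscles overlapped in 5 genes higher in both, among them Sox14, Maats1, Mfhas1 and Ank2, and 2 lower in both, Dmd and Ctnna3. Among 16178 genes tested in both, independent lists would share 0.104 higher and 0.0595 lower genes (Fisher's exact test, p = 9.03e-09 and 0.00116). Those p-values hold only if chance values of the libraries were independent between the muscles. In the gastrocnemius, chosen after their values were seen, Mfhas1 rose by 1.04 (SE 0.13) and Ank2 by 0.41 (SE 0.07) on the log2 scale, and Dmd changed by -0.64 (SE 0.15, adjusted p = 0.0429). Maats1 had a count ratio of 22.8 (95% counting interval 11.7 to 50.7) there. Dmd lost its gastrocnemius call without control 1, 5 or 8 or knockout 6, 7 or 9 (0.0621 to 0.119). Of 602 gastrocnemius calls tested in soleus, 535 (88.9%) had the same sign, against 65.5% over all genes tested in both. Those higher in gastrocnemius by a median log2 of 0.76 had a soleus median of 0.34, those lower by -0.39 a soleus median of -0.11. The overlap counted 73 genes with DESeq2, 27 without a low-count filter, 28 without soleus knockout library 35 and 3, 3 and 4 without soleus controls 34, 37 and 38.

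**Figure D4:**
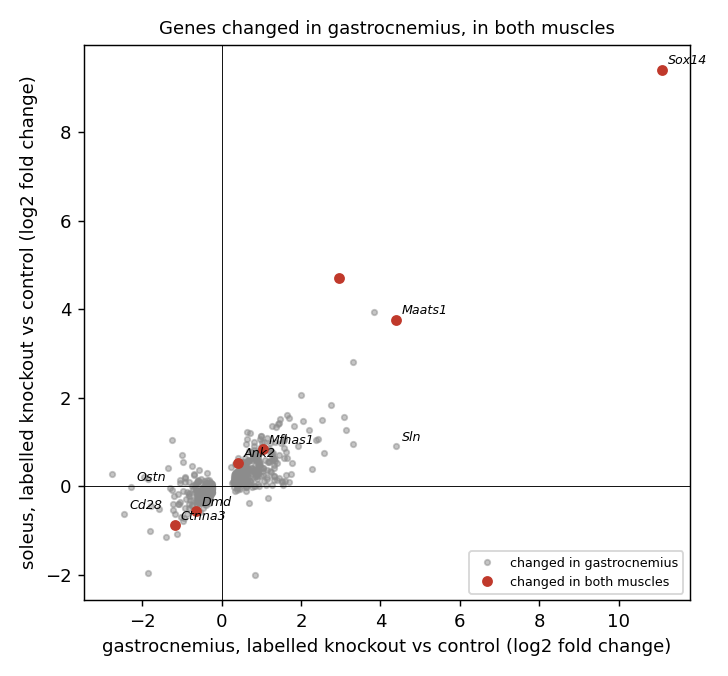
Log2 fold change (labelled knockout against control) in gastrocnemius (x axis) and soleus (y axis) of each gene changed in gastrocnemius, with those changed in both muscles in red. Of 602 such genes 535 have the same sign in both.

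The effect of the knockout label differed between the muscles for 13 of 18494 genes, 11 of them with a higher value in soleus than in gastrocnemius. Cd28 changed by -2.47 in gastrocnemius, from 4.89 ± 0.504 to 0.882 ± 0.257 CPM, and lay at 2.95 ± 0.482 and 1.87 ± 0.367 CPM in soleus (difference 1.82, SE 0.27, adjusted p = 0.0133). Lrtm1 lay at 32.7 ± 6.97 and 73 ± 12 CPM in gastrocnemius but at 58.3 ± 6.12 and 48 ± 7.9 CPM in soleus (difference -1.43, SE 0.21, adjusted p = 0.0146). The phosphate exporter Xpr1 lay at 182 ± 16.7 and 117 ± 12.2 CPM against 59.1 ± 3.4 and 61 ± 4.3 CPM (difference 0.69, SE 0.11, adjusted p = 0.0186), and Cbfb, a partner of the RUNX factors, at 108 ± 9.82 and 69.4 ± 1.91 against 22.9 ± 0.369 and 23.7 ± 3.56 CPM (0.70, SE 0.11, adjusted p = 0.0186). Further differences were found for Bex1 (1.12), C2cd4c (2.61), the integrin Itga4 (1.51), Mrvi1 (-0.83) and Otog (2.28), with adjusted p from 0.0294 to 0.0344. Slc4a10 had 0 counts in all soleus controls, so its fitted difference of 6.60 depends on the prior count. Pcx (0.57, adjusted p = 0.038) and Ostn (2.26, adjusted p = 0.038), chosen after their values were seen, differed too, Ostn lying at 10.7 ± 2.76 and 10.6 ± 3.53 CPM in soleus.

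Of all 18494 genes, 999 had an unadjusted p under 0.05 for this difference, and the counts were 52 with DESeq2, 27 with 1 surrogate variable and 8 at a log2 difference of at least 1. Without 1 gastrocnemius library the count was 3, 6, 5, 3 and 8 (controls 1, 3, 4, 5 and 8), 3 (knockout 6) and 23 (knockout 2). Without 1 soleus library it was 6, 4, 2, 3 and 7 (controls 34, 36, 37, 38 and 41), 3 (knockout 39) and 21 (knockout 42). Cd28 and Lrtm1 passed in all 25 alternatives. Xpr1 lost its call without gastrocnemius knockout 6, soleus control 37 or soleus knockout 39 (adjusted p = 0.0507 to 0.0533), and Cbfb without those or gastrocnemius control 1 or 5 or soleus control 38 (0.0507 to 0.0539). The calls of Bex1 (in 9 of 25 alternatives, adjusted p = 0.0507 to 0.0792), C2cd4c (10, 0.0505 to 0.0893), Itga4 (11, 0.0507 to 0.0865) and Mrvi1 (15, 0.0533 to 0.0865) were lost more often. So were those of Slc4a10 (15, 0.0505 to 0.115), Otog (15, 0.0552 to 0.115), Pcx (16, 0.0505 to 0.108) and Ostn (19, 0.0515 to 0.148). Each of the 18 libraries, when left out, ended at least 1 of these calls.

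Between the control muscles, slow-fibre and lipid oxidation genes were higher in soleus and fast-fibre and glycolytic genes higher in gastrocnemius. Mbtps1 differed by 0.04 (SE 0.07, adjusted p = 0.684), with the opposite sign under RLE scaling (-0.003). Slow-fibre genes rose in 16 of 16 members (median log2 difference 3.86, camera adjusted p = 4.08e-48), such as the slow calcium pump Atp2a2 (263 ± 42.7 in gastrocnemius and 3800 ± 281 CPM in soleus, n = 5 each) and Myoz2 (3.02, SE 0.10). Fast-fibre genes fell in 16 of 18 (median -2.04, 1.08e-22), such as the fast myosin Myh4 (82800 ± 5260 and 1950 ± 1570 CPM), while 1 rose, the IIa myosin Myh2 (3310 ± 113 and 15500 ± 1070 CPM). Fatty acid oxidation genes rose in 26 of 26 (median 0.99, 3.55e-25), among them lipoprotein lipase Lpl (588 ± 17.9 and 2010 ± 131 CPM) and the fatty acid transporter Cd36 (1.42, SE 0.08). Glycolysis and glycogen genes fell in 18 of 27 and rose in 6 (median -1.43, 2.12e-19), with glycogen phosphorylase Pygm at 9080 ± 363 and 1920 ± 211 CPM and Phkg1 at 342 ± 11.4 and 55.1 ± 8.41 CPM. These 4 lists also passed with an estimated correlation (adjusted p = 0.000554, 0.0293, 0.0435 and 0.0293 with an estimated correlation). Endothelial markers rose in 11 of 12 (0.50, adjusted p = 0.0146; adjusted p = 0.292 with an estimated correlation), such as Pecam1 (0.41, SE 0.06). Golgi transport genes fell in 13 of 24 and rose in 3 (-0.20, 0.00901; adjusted p = 0.382 with an estimated correlation), and fibroblast markers fell in 7 of 12 (-0.75, 0.0072; adjusted p = 0.676 with an estimated correlation), such as Clec3b (-1.08, SE 0.10). Counts adjusted over the list alone were the same for these 7 lists.

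The highest soleus values by the naming rule belonged to Mhrt (log2 difference 6.39), whose exons overlap those of the abundant Myh7 on the other strand, Sim1 (5.13), Tecrl (5.05), Sln (4.97), Slc7a15 (4.60) and Sv2b (4.5). The lowest belonged to Mybph (-7.95), Odf3l2 (-7.30), Mstn (-6.41), Mss51 (-6.12), Cntnap2 (-5.77) and Myh4 (-5.42), with adjusted p of at most 9.89e-05 in all 12. Mstn lay at 1.04 ± 0.421 CPM in soleus and Mss51 at 1.75 ± 0.495. In all, 9122 of 18494 genes differed (5074 higher and 4048 lower in soleus), 3025 by at least 2-fold. The balance of directions depended on the fit, with 4647 higher and 4445 lower under RLE scaling, 4887 and 4594 with DESeq2 and 4623 and 4599 with control libraries only. The transcription factor Esrrg (30.8 ± 3 and 160 ± 12.7 CPM) and mitochondrial Idh2 (199 ± 38.2 and 859 ± 116 CPM) were higher in soleus, and Srebf1 (-0.83, SE 0.10) was lower. Other lists missed the camera threshold, with adjusted p of 0.121 for S1P substrates (3 higher, 12 lower of 18), 0.426 for cholesterol synthesis (4 and 8 of 25), 0.9 for fatty acid synthesis (6 and 7 of 20), 0.95 for ER chaperones (5 and 4 of 22). They were 0.801 for the integrated stress response (6 and 5 of 24) and 0.121 for lysosomal genes (8 and 17 of 36). Others were 0.117 for oxidative phosphorylation (34 and 6 of 78), 0.468 for mitochondrially encoded mRNAs (1 and 3 of 13), 0.122 for mitochondrial regulators (13 and 6 of 24). They were also 0.159 for the TCA cycle (11 and 3 of 20), 0.121 for TGF-beta signalling (6 and 14 of 34) and 0.121 for atrophy genes (4 and 11 of 26).

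For denervation genes the adjusted p was 0.199 (4 higher and 10 lower of 23 in soleus), for the matrix 0.0517 (2 and 10 of 26), for macrophage markers 0.214 (0 and 4 of 12). For lymphocyte markers it was 0.962 (0 and 1 of 8), for adipocyte markers 0.426 (4 and 2 of 13) and for satellite cell markers 0.413 (2 and 0 of 10), among them the Notch target Hes1 (log2 difference 1.32, SE 0.19). For Schwann cell markers it was 0.199 (0 and 4 of 12), for smooth muscle 0.801 (3 and 1 of 10), for tendon 0.9 (2 and 3 of 10), for red blood cell genes 0.801 (1 and 0 of 7). For immediate-early genes it was 0.9 (2 and 2 of 18), for clock genes 0.463 (3 and 3 of 16) and for sex-linked genes 0.177 (3 and 0 of 4). Adjusted over the list alone, the counts differed for S1P substrates (4 and 12), lysosomal genes (8 and 18), oxidative phosphorylation (34 and 7), mitochondrially encoded mRNAs (1 and 2), TGF-beta signalling (8 and 14), macrophages (0 and 2), lymphocytes (0 and 0) and Schwann cells (0 and 1). Median, mean and test differed in sign for ER chaperones (0.01, 0.07, down), the integrated stress response (-0.07, 0.14, up), lymphocytes (0.17, -0.05, down), smooth muscle (-0.01, 0.05, up) and immediate-early genes (0.14, 0.08, down).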

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

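The tests of the chromosome segment, of fibre share, of single libraries and of genes over 1 Mb were chosen after the results they weigh were seen, while those of 4 related Sox genes and of the longest exons were set beforehand. In 21 of 278 groups of a named gene or of a library measure such as total counts, 1 library lay far from the others of its group by Dixon's ratio, and chance names about 1 in 20 groups. All of those found were groups of a named gene. Among gastrocnemius libraries labelled knockout these were Rgs2 in library 2 (5.27 CPM; others 9.45 to 9.9), Calm3 in 2 (347; 322 to 326), and Ostn (1.64; 2.94 to 3.19), Timp1 (1.64; 0.819 to 0.95) and Scn4a (625; 730 to 739) in 7. Among gastrocnemius controls they were Sv2b in 1 (0.515; 0.133 to 0.215), Dmd (351; 229 to 265), Pygm (8450; 9170 to 9380) and Asb5 (105; 125 to 133) in 3, and Cgref1 (1.69; 0.93 to 1.09) and Asb14 (64.5; 70.2 to 71.7) in 4. Among soleus libraries labelled knockout, library 40 stood apart for Myl2 (569; 860 to 877) and Dmd (225; 285 to 293). Among soleus controls they were Sox14 (0.0163, which is 1 count; 0 in the others), Sln (9.99; 16.2 to 18.6) and Dmd (425; 397 to 404) in 34, Gnptab (11.2; 12.8 to 13.4), Catsperg1 (0.259; 0.599 to 0.685) and Mybph (0.917; 0.351 to 0.511) in 38, and Srebf1 (31.3; 25.9 to 27.1) and Myh2 (13700; 15500 to 16200) in 41.

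A second reason for a closer look was an effect of the knockout label that differed between the muscles by the interaction test. The differences (soleus minus gastrocnemius, log2) were 1.822 for Cd28, 0.691 for Xpr1, 6.595 for Slc4a10, 1.514 for Itga4, 1.122 for Bex1, 2.28 for Otog, -0.832 for Mrvi1, 2.606 for C2cd4c, 0.697 for Cbfb, -1.435 for Lrtm1, 2.259 for Ostn and 0.568 for Pcx. Only Cd28 and Lrtm1 passed in all 25 alternatives, and each of the 18 libraries, when left out, ended at least 1 of the other 10 calls.

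Sox14 was counted in every library labelled knockout and, apart from 1 count, in no control. Reads from Sox1, Sox2, Sox3 or Sox21, the relatives examined, are excluded as its source, since the highest of these 4 reached 1.6% of the Sox14 mean. A change of the surrounding chromosome segment, such as an inserted transgene or a strain-specific segment carried with the Cre allele, could give the same pattern. Among all genes, 4 went from 0 counts in all gastrocnemius controls to at least 5 in each library labelled knockout (Sox14, A4gnt, Fgl1 and Gm5083), and A4gnt lies 252 kb from Sox14; of 13 other genes within 500 kb, 4 were tested and 0 passed, with log2 fold changes from -0.183 to 0.117. Whether Sox14 follows from the loss of S1P or from the Cre allele stays open, because no control carrying Cre alone stands among the libraries.

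Matrix, macrophage and regeneration genes were higher as lists in both muscles by camera at the preset correlation, but not with an estimated one (adjusted p = 0.631, 0.631 and 0.293 with an estimated correlation in gastrocnemius, and 0.502, 0.502 and 0.458 in soleus), while exact permutation of the scores gave p = 0.0397, 0.0238 and 0.00794 in gastrocnemius and 0.127, 0.0873 and 0.00794 in soleus. A lower share of muscle fibre RNA would raise all cell type markers alike. In soleus the macrophage score rose beyond the mean of other cell types (exact permutation p = 0.0397, unadjusted). The macrophage list was picked for being higher in these libraries, and its score alone missed 0.05 in soleus (exact permutation p = 0.0873). Soleus medians were 0.257 for fibroblast, -0.057 for endothelial, -0.471 for Schwann cell, -0.147 for smooth muscle and -0.131 for tendon markers. Part of the difference therefore came from lower values of other cell types. The test does not decide whether a lower fibre share raised macrophage markers, and it does not bear on the matrix list. In gastrocnemius the same test could not tell (exact permutation p = 0.0873). Medians there were 0.174 for fibroblast, 0.1 for endothelial, -0.209 for Schwann cell, -0.096 for smooth muscle and -0.001 for tendon markers. Immature or denervated fibres express the regeneration genes, and a lower fibre share would not raise those that fibres alone express. The list is not limited to such genes, since Myf5 also stands among the satellite cell markers. Of 23 in gastrocnemius 8 rose and 3 fell. That argues against a lower fibre share only for members that fibres alone express, and which cells raised each member was not tested. Gastrocnemius knockout library 7 alone does not account for the pattern, since the matrix median without it was 0.248. Without soleus knockout libraries 40 and 42 the matrix median was 0.041. Those 2 libraries were picked for their high list scores, so a lower median without them was to be expected and decides nothing. For the regeneration list the soleus permutation p of 0.00794 is the smallest that 126 splits can give. It requires every soleus library labelled knockout to score above every control, so the direction of that list was not that of those 2 libraries alone. As many lists of any kind were called in 26 of 100 splits of the libraries in gastrocnemius and 36 of 100 in soleus, the real one included. These counts do not say which lists were called, so they do not test the matrix, macrophage or regeneration lists. Whether injury or inflammation that differs between single mice gave the pattern without any effect of S1P was not tested and stays open.

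Several of the lower genes span very long stretches of the genome. Of 38 tested genes over 1 Mb, 4 were lower in gastrocnemius (Macrod2, Dmd, Cntnap2 and Ctnna3), and of 40 in soleus 2 were (Dmd and Ctnna3), a class drawn up after these genes were seen, so that its size carries no test. A fall of all genes over 1 Mb is excluded, since their median log2 fold changes were -0.048 in gastrocnemius (quartiles -0.366 to 0.234) and -0.032 in soleus (-0.243 to 0.162). The 10% of genes with the longest exons had medians of 0.025 and -0.009, which argues against a loss of long transcripts as a class. A median over so many genes cannot exclude loss of a few very long transcripts. What sets these genes apart stays open, no biological explanation was tested, and their calls are weak: in gastrocnemius Macrod2 lost its call without control 1, 3, 4 or 5 or knockout 6 or 7 (adjusted p = 0.0558 to 0.106), Dmd without control 1, 5 or 8 or knockout 6, 7 or 9 (0.0621 to 0.119), Cntnap2 without control 5 or knockout 6 (0.0575 and 0.0775) and Ctnna3 without control 1 or 5 or knockout 7 (0.0596 to 0.0655), and in soleus Dmd without any 1 control (0.0548 to 0.0843) and Ctnna3 without control 34, 36, 37 or 38 or knockout 40 (0.0725 to 0.118), both also with 1 surrogate variable (0.0842 and 0.0746), the fit of all 18 libraries (0.0581 and 0.0781), the Ttn share as covariate (0.724 and 1) and without libraries 40 and 42 (0.0579 and 0.181).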

How the results depend on the processing

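The tests that use the share of counts from Ttn and those without soleus knockout libraries 40 and 42 were chosen after the data were seen. Across 125 pairs of a named gene and a comparison, alternatives gave 2268 values: 1956 kept direction and side of the threshold, 271 were weaker, 23 stronger and 18 had the opposite sign. In gastrocnemius, against 619 genes, a log2 fold change of at least 1 left 132, while DESeq2 called 1235, voom 1028, 1 surrogate variable 1163 and the Ttn share as covariate 1189. In soleus, against 10, the same settings gave 6, 166, 10, 4 and 3, with 48 without a low-count filter, 28 in the fit of all 18 libraries and 5 without knockout libraries 40 and 42. Between the muscles 3025 of 9122 were left at a log2 difference of at least 1. For the difference of knockout effects, against 13, there were 8 at that limit, 52 with DESeq2, 27 with 1 surrogate variable and 32 with a block on the title number, 10 of them among the 13. For calls in both muscles, against 7, there were 3 at that limit, 73 with DESeq2 and 27 without a low-count filter. Leaving out 1 library gave 206 to 1080 genes in gastrocnemius, 3 to 66 in soleus, 8360 to 9213 between the muscles, 2 to 23 for the difference and 3 to 28 in both muscles. Gene lists called in gastrocnemius numbered 12, against 0 with an estimated correlation and 4 with fry (10 to 14 without 1 library). The lists that passed fry there were Golgi transport, lymphocyte and satellite cell markers (adjusted p = 0.023 each) and clock genes (0.0478). Denervation genes (fry adjusted p = 0.0532), the matrix and macrophage markers (0.243 each) missed. Gene lists called in soleus numbered 13, against 0, 0 and, without libraries 40 and 42, 8 (10 to 16). Between the muscles they numbered 7, against 4 with an estimated correlation, 17 with fry and 17 without a low-count filter (7 to 9). The mixed test of fry, which asks for changes in either direction, passed for 14, 0 and 30 lists. The values with the opposite sign all belonged to genes that missed the threshold. In soleus Mstn (0.15) was -0.022 with the Ttn share, -0.078 without control 37 and -0.126 without knockout 39, up to 0.501 without knockout 42. Srebf1 there was -0.001 with 1 surrogate variable, and Srebf2 -0.016 with the Ttn share and -0.049 without libraries 40 and 42. Atf6 (-0.002) was 0.01 with voom, 0.067 with 1 surrogate variable, 0.025 with the Ttn share, 0.032 without libraries 40 and 42, and -0.048 (without control 41) to 0.028 without 1 library. Mbtps1 between the muscles (0.04) was -0.003 with DESeq2 and with RLE scaling and -0.004 with control libraries only. Fewer libraries lower the power of every test without 1 library, and for the rest the cause was not tested. The title numbers of the muscles run in parallel (soleus number minus 33), and same-number libraries correlated at 0.08 to 0.44 over 9 pairs, 6 of them best with their own number, a hint from the data and not a stated pairing. A sex covariate was not run, since the condition set for it beforehand was not met. Depth limits genes at a few counts, such as A4gnt and Fam71e2, whose ratios carry wide counting intervals.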

Other observations

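Apart from Chrng and Chrna1, the genes and lists of the first 2 paragraphs were chosen after the data were seen, while the splits of the libraries were set beforehand. In gastrocnemius, further genes outside the naming rule changed in the libraries labelled knockout. Lower were the calmodulin gene Calm3 (log2 fold change -0.41, adjusted p = 0.00433) and Mylk2, the calmodulin-dependent kinase of the fast myosin light chain (866 to 564 CPM, -0.62, SE 0.09, adjusted p = 0.00234). The growth factor gene Egf fell from 32 ± 0.446 (SD, n = 5) to 15.6 ± 2.96 CPM (SD, n = 4; -1.03, SE 0.11, adjusted p = 0.000605). Of 16 tested genes of the Asb family, which carry substrates to ubiquitin ligases, 5 fell and 0 rose by edgeR, among them Asb5 (-0.74, adjusted p = 0.00118), Asb10 (-0.53, adjusted p = 0.00484) and Asb14 (-0.59, adjusted p = 0.00389). Asb5 missed the threshold in the fit of all 18 libraries (0.0651). The retinoid receptor gene Rxrg fell (-0.58, SE 0.09, adjusted p = 0.00423), whereas acetylcholinesterase, Ache (46.4 to 68.3 CPM, 0.56, adjusted p = 0.0036), and the receptor subunit Chrna9 (3.30, SE 0.53, adjusted p = 0.00472) rose, as did Chrng and Chrna1 of the denervation list.

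Between the effects of the knockout label in the 2 muscles, 7 of the 32 lists differed by camera at the preset correlation and 0 with an estimated correlation. Higher in soleus than in gastrocnemius were mitochondrially encoded mRNAs (median difference 0.25, adjusted p = 3.03e-06; adjusted p = 0.605 with an estimated correlation), fast-fibre genes (0.25, 3.03e-06; adjusted p = 0.605 with an estimated correlation) and Golgi transport genes (0.09, 0.000989; adjusted p = 0.605 with an estimated correlation). So were glycolysis (0.10, 0.00544; adjusted p = 0.609 with an estimated correlation), oxidative phosphorylation (0.07, 0.0275; adjusted p = 0.917 with an estimated correlation) and TGF-beta signalling (0.11, 0.0455; adjusted p = 0.609 with an estimated correlation). Endothelial markers were lower (-0.12, 0.0406; adjusted p = 0.605 with an estimated correlation).

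Of the possible splits of the libraries into groups of the same sizes, 100 were drawn, the real one included. The real split called the most genes in gastrocnemius (619, highest other 17), in soleus (10, highest other 5) and for the difference (13, highest other 4). It also gave the most calls shared by the muscles (7, highest other 2). Its correlation of changes over all genes was the highest by a narrow margin (0.523, highest other 0.508, median of the others 0.216). For each of these, 1 of 100 splits, the real one, reached the value. That argues against chance but does not exclude it, least of all for the correlation. The share of all genes with the same sign in both muscles did not stand out in this way (65.5%, highest other 65.7%). Between the muscles (9122, highest other 997), every other split of the controls put both muscles into each group. The muscle difference then adds to the spread within groups, so this count does not test chance. Chance cannot be excluded for the number of lists called in gastrocnemius (12, highest other 18), in soleus (13, highest other 19) or between the muscles (7, highest other 19), where 26, 36 and 90 of 100 splits reached the real value, the real one included.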
